A study of Mus musculus with 4 samples.

How the data were processed

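Chromatin accessibility was measured by ATAC-seq in sorted hair follicle stem cells of 2 genotypes, a Foxc1 knockout and a control, with 1 library per genotype sequenced in 2 runs each (4 runs). Groups were taken from the genotype labels, and the resequenced runs were counted as the same library. The 4 runs share 1 list of accessible regions, so no value could be given to a genotype or a run, and the comparison of knockout with control that had been planned was not made. Whether the list was called on pooled reads or merged from separate lists is not given in the sources used here.

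The authors deposited region coordinates (chromosome, start and end) with no score, summit, fold enrichment or read count. Per the submitters' processing notes, Bowtie2, MACS2 and bedtools were used with the mm10 build; their versions, settings, read filters and any Tn5 offset are not given in the sources used here. The number of reads is not given either, so peak width was the only property of a peak that could stand in for strength, and weak or absent peaks cannot be separated from low depth. Starts were converted to 1-based positions. No filter was applied, except that the peak covering the whole mitochondrial chromosome (16299 bp) was left out of every comparison with random placements. No columns of per-sample values were left unused (0).

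Gene positions came from a RefSeq gene table of assembly GRCm38.p6, whose primary coordinates are those of mm10, with 49980 genes on chromosomes, 21887 of them protein-coding and outside the mitochondrial chromosome. As a check of the coordinates, 15.6% of peak midpoints lay at protein-coding gene ends, against 4.35% after shifting all peaks by 10000 bp and 3.98% after 100000 bp. The table holds gene bounds without strand or transcripts. The planned promoter class was therefore replaced by the gene end, within 1000 bp of either bound of a gene, and the planned classes of exons, introns and untranslated regions by the interior of genes. The planned analyses of 36 motifs, of short sequence words, of forkhead motifs at stem cell genes and of motif pairs need the genome sequence and were not run. Random placements stayed between the first and last annotated or accessible base of each chromosome, because assembly gaps were not used here.

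Each peak was put by its midpoint in the first of 5 classes that held: protein-coding gene end, other gene end, inside a protein-coding gene, inside another gene, between genes. Shares were compared with 1000 random placements of the peaks on their own chromosomes (200 for the alternative settings), giving two-sided permutation p-values. A total of 18 gene lists had been fixed before the data were examined: 5 of skin epithelium and its appendages (hair follicle stem cell, basal keratinocyte, epidermal differentiation, sebaceous gland, hair shaft and root sheath), 4 of other skin cells (dermal fibroblast, melanocyte, immune cell, endothelial cell), 4 of cell types not expected in the sort (neuron, hepatocyte, skeletal muscle, pluripotency and germline), and housekeeping, BMP and TGF-beta signalling, WNT signalling, cell cycle and cell cycle inhibitor genes. All listed genes were found in the table by symbol except Krt85. Lists share some members, and members shared with the stem cell list were left out of both sides when lists were compared with it.

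A gene had an end peak when a peak shared at least 1 base with either end window, and lists were compared with all other protein-coding genes by two-sided Fisher's exact tests. Odds ratios were computed with 0.5 added to each of the 4 counts, which draws them towards 1. A distal peak had its midpoint over 1 kb from every annotated gene end and went to the protein-coding gene with the nearest end, up to 50 kb away. Since an end peak is counted by overlap and a distal peak by midpoint, a wide peak can count as both. A gene's territory was the ground nearer to its ends than to those of any other protein-coding gene. It reached at most 50 kb from each end and left out the 1 kb windows around all annotated gene ends. Peaks inside a long gene but over 50 kb from both its ends were thus not counted for it. The median count of a list was compared with 10000 random lists matched on territory size in 20 bins, and the stem cell list was compared with each other list by 100000 permutations of territory-matched percentiles. Clusters joined peaks with gaps under 12.5 kb and were compared with 100 random placements. P-values were adjusted by Benjamini-Hochberg over the 18 lists, the 17 comparisons of lists or the 5 classes, with a threshold of 0.05. Shares have Wilson or exact Clopper-Pearson 95% intervals, which cover counting error only.

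Named genes followed a rule fixed in advance: 21 genes of stem cell biology whatever their values, list members with no end peak (up to 5, otherwise the first 4 in alphabetical order), the 10 protein-coding genes with the most distal peaks and the 10 clusters with the most peaks. Other genes, including examples with an end peak and the highest distal counts of a list, were chosen after their values were seen. Some genes that the rule names are not reported here. Alternatives planned in advance were 500 and 2500 bp around gene ends, any overlapping base for classes, midpoints for end peaks, peaks at or above the median width, 20 and 100 kb for distal peaks, unmatched random lists, gaps of 5 and 25 kb, and autosomes with X only. On simulated data, random peaks gave a fold of 0.994 at protein-coding gene ends. The gene end test called 4% of random lists of 25 genes and 92% of lists with 30 points more end peaks. The distal test called 0% of unchanged lists, 26.7% with a true 2-fold and 58.3% with a true 3-fold count. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.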

Results

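Open chromatin was mapped by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into accessible DNA, in hair follicle stem cells of mouse back skin. The cells came from female mice at postnatal day 30 and were sorted as positive for a histone 2B-GFP reporter driven by the Krt14 promoter, negative for Sca-1, and positive for CD34 and for CD49f, the integrin encoded by Itga6. The series holds 2 genotypes, a Foxc1 knockout, in which a Krt14-driven Cre recombinase removes the floxed Foxc1 alleles, and a control with the same floxed alleles and reporter but no Cre. Foxc1 encodes a forkhead transcription factor. Each genotype was 1 library that was sequenced in 2 runs, so there was no biological replicate. The values used here were a single list of regions for the whole series, with coordinates on mm10 and no score, read count or genotype for any region. Peaks of the knockout and of the control could therefore not be told apart, no comparison between them was made, and the read depth behind each peak is unknown. All p-values below describe this one peak list, in which genes and peaks are not replicates.

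The list held 74777 accessible regions, of which 74705 lay on the 19 autosomes and the X chromosome. They covered 58.9 Mb there, 2.25% of the ground considered. Autosomes carried between 25.2 peaks per Mb on chromosome 14 and 33.8 on chromosome 19, with a median of 29.7. The X chromosome, of which 1 copy is inactivated in female cells, carried 15.8 peaks per Mb, below all 19 autosomes, and its peaks had a median width of 412 bp. The median width over the list was 587 bp (quartiles 341 and 1025 bp). The smallest width was 200 bp, shared by 4873 peaks or 6.52%, and no peaks overlapped. Across the 19 autosomes, peak density and the density of protein-coding genes had a Pearson r of 0.349 (permutation p = 0.144) and a Spearman rho of 0.496 (permutation p = 0.0322). Without the 2 chromosomes farthest from the median gene density the values were 0.530 and 0.591.

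Accessible regions were concentrated at the ends of protein-coding genes. A total of 11669 of 74776 peaks, or 15.6% (95% Wilson interval 15.3 to 15.9), had their midpoint within 1 kb of an annotated end of a protein-coding gene, compared with 3.04% ± 0.0651 (SD over 1000 random placements), a 5.13-fold excess. Ends of other annotated genes, such as non-coding RNAs and pseudogenes, held 5.04% of peaks, 1.56-fold above the placements. Ground between genes held 34.6% of peaks against 49.5% of random placements, 0.700-fold. The interior of protein-coding genes held 38.3% against 37.3%, and the interior of other genes 6.43% against 6.93%. Each of the 5 classes had a two-sided permutation p of 0.002, the smallest that the placements could give, also after adjustment. Peaks at protein-coding gene ends were also wider, with a median of 1190 bp against 461 bp between genes, a difference of 729 bp (permutation p = 0.0001, the smallest possible). The gene table gives no strand, so the end at which transcription starts was not known. The 1.03-fold excess inside protein-coding genes was the only direction that depended on the setting, since it became 0.896-fold when each peak was placed at random within 500 kb of its own position and 0.977-fold with 2500 bp around gene ends.

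**Figure D1:**
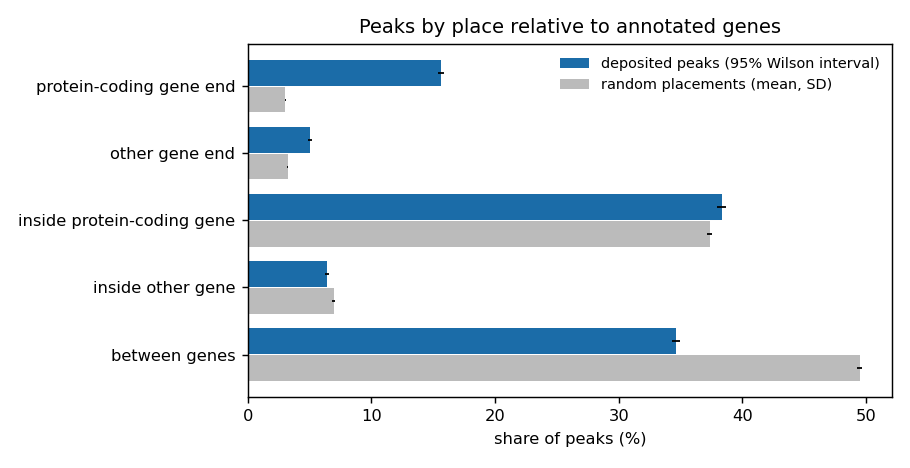
Share of peaks (%, horizontal axis) in each of 5 classes of place relative to annotated genes; blue bars are the deposited peaks with 95% Wilson intervals and grey bars the mean and SD of 1000 random placements. Protein-coding gene ends hold 15.6% of peaks against 3.04% at random, and ground between genes 34.6% against 49.5%.

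Genes that mark hair follicle stem cells and basal keratinocytes mostly had an accessible end, as did housekeeping, cell cycle and BMP and TGF-beta genes, and genes of 7 lists of other cell types mostly did not. Of 28 hair follicle stem cell genes, 25 (89.3%, exact 95% interval 71.8 to 97.7) had a peak within 1 kb of either end, against 57.5% of the other protein-coding genes (odds ratio 5.38 with 0.5 added to each count, Fisher's exact test, adjusted p = 0.00241 over 18 lists). These 25 included the transcription factor genes Sox9, Lhx2, Nfatc1, Foxc1, Tcf7l1 and Tbx1, the surface marker Cd34, the receptor gene Lgr5 and the keratin gene Krt15. Nfix, Runx1 and the secreted WNT pathway modulator Dkk3 had none. Of 24 basal keratinocyte genes, 21 had an end peak (87.5%), among them Krt5, Krt14, Itga6, Itgb4 and the laminin genes Lama3 and Lamb3. Ehf, Tfap2c and Trp63, the gene of the epithelial master regulator p63, had none.

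Genes of BMP and TGF-beta signalling, a list that holds ligands, receptors, antagonists and targets, had end peaks in 24 of 27 cases, including Bmp2, Bmp4, Bmp6, the receptor gene Bmpr1a and the target genes Id1, Id2 and Id3; Chrd, Fst and Tgfb2 had none. Cell cycle genes had them in 22 of 25 cases, among them Mki67, Cdk1 and Ccna2, and lacked them at Birc5, Ccnb2 and Ccnd1. Housekeeping genes had them in 19 of 20 cases, the exception being Ywhaz. For these 3 lists and the basal keratinocyte list, the adjusted p ranged from 0.00241 for housekeeping to 0.00759 for basal keratinocyte (Fisher's exact test). The same tests placed 7 lists below the other protein-coding genes. They were hepatocyte (3 of 20, adjusted p = 0.00235, Fisher's exact test), pluripotency and germline (2 of 14), endothelial cell (4 of 17), skeletal muscle (4 of 17), melanocyte (4 of 16), immune cell (6 of 21) and neuron (5 of 18). Members with no end peak included Ahsg, Alb, Apoa1 and Apoc3 of the liver, Ddx4, Dppa3, Dppa4 and Dppa5a of germline and early embryo, Ednrb, Gpr143, Kit and Mc1r of melanocytes, and Aif1, Cd207 and Cd3d of immune cells. Likewise Cdh5, Cldn5, Egfl7 and Emcn of endothelium, Acta1, Cacna1s, Des and Myf5 of muscle, and Camk2a, Gad1, Gad2 and Gria1 of neurons had none.

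The other 6 lists, of WNT signalling, cell cycle inhibitors, sebaceous gland, epidermal differentiation, hair shaft and root sheath, and dermal fibroblasts, did not pass the threshold. WNT signalling genes had end peaks in 21 of 27 cases (adjusted p = 0.0682, Fisher's exact test), with Axin1, Axin2, Dkk3 and Lrp5 among those without. Cell cycle inhibitors had them in 10 of 12 cases, all but Cdkn1a and Cdkn1c, and sebaceous gland genes in 9 of 14, lacking them at Awat1, Cidea, Far2, Krt79 and Pparg. Epidermal differentiation genes had them in 11 of 24 cases, with Alox12b, Cnfn, Flg and Flg2 among those without. Hair shaft and root sheath genes had them in 7 of 19 cases, with Dlx3, Gata3, Krt27 and Krt31 among those without. Dermal fibroblast genes had them in 7 of 18 cases, with Col3a1, Crabp1, Dpt and Fap among those without. Set directly against the other 17 lists, the hair follicle stem cell genes had end peaks more often than 10 of them. They were not told apart from basal keratinocyte, housekeeping (adjusted p = 0.766, Fisher's exact test), cell cycle, cell cycle inhibitor, BMP and TGF-beta, WNT signalling or sebaceous gland genes. Over all 21887 protein-coding genes, 12600 (57.6%) had an end peak, 10818 of them at 1 end only. Gene bounds span all transcripts, so a peak at a transcript start inside a gene is not counted as a gene end. With 2500 bp around gene ends only 3 lists lay below the other genes, and among genes with no other gene end within 2 kb none (0) did.

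**Figure D2:**
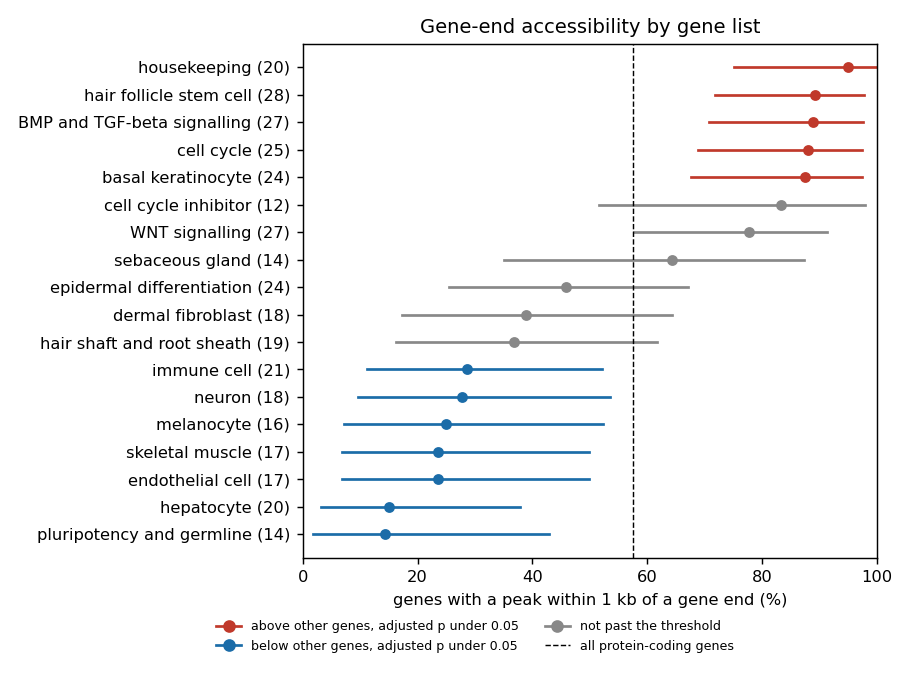
Share of genes with a peak within 1 kb of either gene end (%, horizontal axis) for the 18 gene lists, with the number of genes in parentheses; points are shares, lines exact 95% intervals, and the dashed line marks the 57.6% of all protein-coding genes. The hair follicle stem cell list stands at 89.3% and the hepatocyte list, with 3 of 20 genes, among the lowest.

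Hair follicle stem cell genes and basal keratinocyte genes were also surrounded by more distal peaks than genes with a similar amount of neighbouring ground. Distal peaks, whose midpoint lies over 1 kb from every annotated gene end, numbered 59340, and 36851 of them (62.1%) were given to the protein-coding gene with the nearest end within 50 kb. The hair follicle stem cell genes had a median of 5.5 distal peaks (quartiles 2 and 8.25), against 1.88 in random lists matched on territory size (95% range 1 to 3; permutation adjusted p = 0.0036). Runx1 had 16, Nfib 14, the WNT antagonist gene Sfrp1 12, Tcf7l1 11 and the growth restraint gene Lrig1 10. Basal keratinocyte genes had a median of 5 against 1.69 (permutation adjusted p = 0.0036), led by Cdh3 and Egfr with 15 each, Itgb1 with 11 and Cdh1 with 10. Epidermal differentiation genes had a median of 1.5 against 0.457 (permutation adjusted p = 0.0576), with 15 at Abca12 and 0 at Krt1, Krt10 and Flg.

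The other 15 lists did not pass the threshold either. Medians were 3 for BMP and TGF-beta signalling and for WNT signalling, 2 for sebaceous gland, endothelial cell and neuron, and 1.5 for cell cycle inhibitors. They were 1 for hair shaft and root sheath, dermal fibroblast and melanocyte, 0.5 for pluripotency and germline, and 0 for immune cell, hepatocyte, skeletal muscle, housekeeping and cell cycle genes. Set directly against the other 17 lists by territory-matched percentile, the hair follicle stem cell genes (mean percentile 77.05) lay above 12 lists after adjustment. They lay 45.1 points above dermal fibroblast and 42.8 above immune cell genes (permutation adjusted p = 4.25e-05 for both), and 16.0 above epidermal differentiation (permutation adjusted p = 0.0303). They were not told apart from basal keratinocyte (difference -6.07, permutation adjusted p = 0.221), hair shaft and root sheath, endothelial cell, BMP and TGF-beta or WNT signalling genes. Among peaks under the median width, where random medians were lower too, the distal difference of the hair follicle stem cell list was 0.462. At a median of 1.5 against 1.04, it did not pass (permutation adjusted p = 0.831). That of the basal keratinocyte list was 0.569 there and did not pass either (permutation adjusted p = 0.748). With distal peaks up to 100 kb BMP and TGF-beta signalling passed, with a median of 6 against 2.33 (permutation adjusted p = 0.0048). The test on the median found 26.7% of simulated lists with a true 2-fold count, at an unadjusted p under 0.05. The lists here were judged by the stricter adjusted p, so a list that did not pass may still differ. Where a list had a median of 0, the random range also began at 0, so this test could not place the list below. By means, dermal fibroblast genes lay below random, at 1 against 2.76 (permutation adjusted p = 0.0336). Immune cell genes did so too, at 0.333 against 1.14 (permutation adjusted p = 0.0468).

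**Figure D3:**
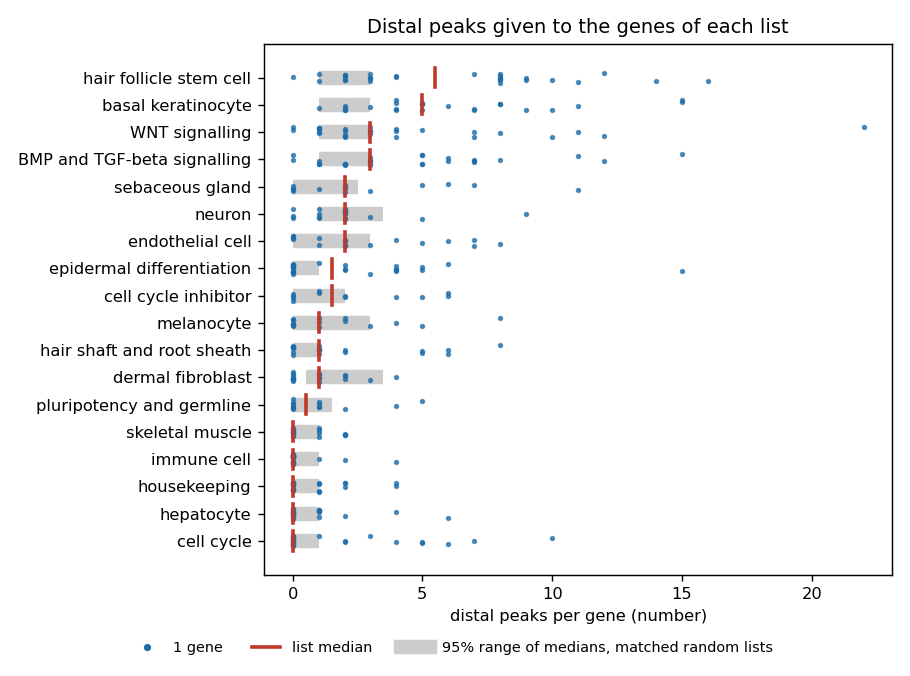
Distal peaks per gene (number, horizontal axis) for the 18 gene lists; blue points are single genes, red bars list medians and grey bars the 95% range of medians of matched random lists. The medians of the hair follicle stem cell list (5.5) and the basal keratinocyte list (5) lie beyond their random ranges of 1 to 3.

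Foxc1, the deleted gene, lies on chromosome 13 from 31806646 to 31810635 (mm10). A peak of 1556 bp, from 31806017 to 31807572, covered its lower-coordinate end, and 2 distal peaks lay 8359 and 9950 bp outside that end. Nfatc1, on chromosome 18 from 80606205 to 80713071, encodes a factor of stem cell quiescence. It had a peak of 4152 bp at its upper-coordinate end and 8 distal peaks, the end peak counted among them because its midpoint lies over 1 kb from the end. That count stood at percentile 85.8 of genes with matched territory. The widest of the peaks inside the gene spanned 3536 bp from 80653879 to 80657414. Sox9, on chromosome 11 from 112782210 to 112787757, had a peak at each end and 2 distal peaks, at percentile 53.3. Lhx2, on chromosome 2 from 38339271 to 38369737, had 9 distal peaks, at percentile 95.2, the widest of them 3892 bp long and 6221 bp beyond the upper-coordinate end. Tcf7l1 had 11 distal peaks, Tcf7l2 7, Foxp1 8 and Lgr5 4. These counts leave out peaks inside a long gene, such as Foxp1, that lay over 50 kb from both its ends. Tbx1 had 3 peaks at its upper-coordinate end, of which 1 was also its only distal peak.

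Runx1, on chromosome 16 from 92601466 to 92826074, had no end peak but its 16 distal peaks stood at percentile 97.2. Trp63, on the same chromosome from 25683763 to 25892088, also had no end peak and 8 distal peaks, of which 4 lay inside the gene, the widest of these from 25842837 to 25845276. Further peaks inside both genes lay over 50 kb from either end and were not counted. Examples are those from 92696526 to 92698418 in Runx1 and from 25834929 to 25835651 in Trp63. Among surface and secreted markers, Cd34 had 3 distal peaks, Fgf18 3, Bmp2 3 and Bmp6 2. The BMP target gene Id1 had 3 and stood at percentile 97.1 in a territory of 18.9 kb. Krt15 had an end peak and 0 distal peaks in a territory of 7.715 kb. Krt5 and Krt14 had 2 distal peaks each and Itga6 had 8. At Cd34, Id1 and Krt14, 1 distal peak each was also counted at a gene end. With coordinates only, any reads from the Krt14 promoter copies in the reporter and Cre constructs could not be told from those of the Krt14 gene itself. Counts per gene depend on the assignment distance, as Nfatc1 had 3 distal peaks and Nfib 4 within 20 kb.

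**Figure D4:**
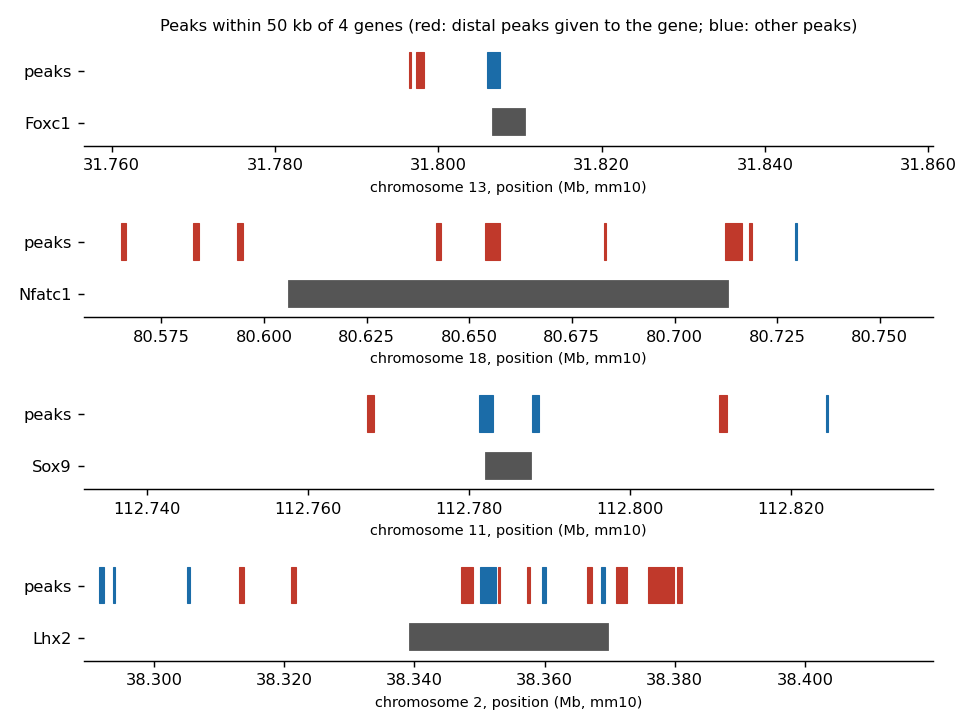
Peaks within 50 kb of Foxc1, Nfatc1, Sox9 and Lhx2, with position in Mb on mm10 on each horizontal axis; grey boxes are the genes, red boxes the distal peaks given to that gene and blue boxes other peaks, which lie at a gene end or were given to a neighbour. Foxc1 and Sox9 have 2 distal peaks each, Nfatc1 8 and Lhx2 9.

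Peaks were also gathered into dense stretches. Joining peaks less than 12.5 kb apart gave 412 clusters of 10 or more peaks, against 2.27 ± 1.60 (SD) in 100 random placements (permutation p = 0.02, the smallest possible). The placements took no account of assembly gaps or of the concentration of peaks at gene ends. The excess of clusters therefore shows only that peaks were spread unevenly. Clusters overlapped 6 of 24 basal keratinocyte genes (Cdh3, Dst, Egfr, Itgb1, Krt17 and Lama3), against 3.39% of other protein-coding genes (Fisher's exact test, adjusted p = 0.00222). They overlapped 3 of 28 hair follicle stem cell genes (Lhx2, Runx1 and the vitamin D receptor gene Vdr; adjusted p = 0.414, Fisher's exact test). They also overlapped 4 of 27 BMP and TGF-beta genes (Grem1, Id1, Smad4 and Smad7; adjusted p = 0.114, Fisher's exact test). The other 15 lists had at most 2 members each in clusters and did not pass. Unlike the distal test, these tests were not matched on gene length or territory. Basal keratinocyte genes had a median territory of 84.6 kb, against 40.6 kb for all protein-coding genes, so gene size may add to their share.

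The clusters with the most peaks lay at other genes. The first, with 170 peaks, spanned Prl2c2 and Prl2c3, members of the prolactin family, on chromosome 13 from 12742568 to 13006247. Chromosome 8 held 3 of the first 10, with 131, 110 and 109 peaks between 20003199 and 20711808, at the provisional genes Gm21119 and Gm40469, at Gm15319 and next to 9530057J20Rik. Chromosome 4 held 3 more, with 114, 111 and 86 peaks at zinc finger genes including Zfp978, Zfp988, Zfp991 and Zfp981. The rest of the first 10 were 111 peaks next to the lower-coordinate end of the autophagy gene Atg7 on chromosome 6, 95 at the nuclear body genes Sp100, Sp110 and Sp140 on chromosome 1, and 80 at Speer4c and Speer4d on chromosome 5. The 10 protein-coding genes with the most distal peaks were Prl2c3 (76), Gm15319 (65), Gm21119 (62), 4930467E23Rik (55), Zfp988 (52), Zfp991 (47), Gm40469 (39), Atg7 (38), Zfp978 (37) and Cwc22 (36). The number of clusters depended on the gap, at 123 with gaps under 5 kb and 1296 with gaps under 25 kb, but exceeded the random mean in both cases.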

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

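Both tests of the chromosome Y peaks were chosen after the peaks had been seen. A total of 71 peaks lay on chromosome Y although all libraries are labelled female. They were kept in the comparisons with random placements. Male cells in the sample could open single-copy Y genes, but 0 of 8 (Ddx3y, Eif2s3y, Kdm5d, Uty, Usp9y, Zfy1, Zfy2 and Sry) had an end peak. Of 7 X-linked partners 5 had one, including Ddx3x, Kdm5c and Usp9x. Zfx and Sox3, the partners of Zfy1, Zfy2 and Sry, had none. Of the 8 Y genes 1, Zfy1, had a peak in or near the gene. With depth unknown, a small share of male cells could go unseen. Reads of the region that X and Y share, placed on Y, could account for much of the signal: 41 peaks lay in the last 200 kb of the accessible ground, from 90650937 to 90835792, and held 88.6% of the accessible bases on Y. That value fell short of the 90% set for the test, and the other 30 peaks, with a median width of 218.5 bp, stay unexplained. No biological explanation was tested.

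Outside the comparisons, 1 peak of 16299 bp covered the whole mitochondrial chromosome.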

How the results depend on the processing

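Of 606 recomputed values, 539 were kept. Some of these could change little or not at all. Leaving out Cd34, Itga6, Krt14 and Foxc1 does not alter the counts of lists without these genes. Placement within 500 kb does not alter the observed number of clusters. The share of values kept therefore overstates how far the results were tested. A tested value was kept if it stayed on its side of the threshold, and a change of direction counted only where either value passed. Other values were kept within their counting error, and numbers of lists, peaks or clusters within a fixed ratio. Settings added after the data had been seen were placement within 500 kb, peaks outside clusters of 40 or more, isolated genes, genes without receptor families or provisional names, lists without Cd34, Itga6, Krt14 and Foxc1, gene body assignment, means, and peaks under the median width. The excess inside protein-coding genes turned to 0.977-fold with 2500 bp around gene ends, 0.999-fold for peaks at or above the median width and 0.896-fold with placement within 500 kb, and was no longer past the threshold at 1.01-fold by any overlapping base. The 7 lists below other genes at gene ends became 3 with 2500 bp and 0 for isolated genes, where fewer genes were tested. The excess of distal peaks at hair follicle stem cell genes fell to 0.462 among peaks under the median width, where 0 lists lay above random. It was 1.5 against 1.04 there and 5.5 against 1.88 over all peaks. With fewer peaks the random value fell too, so the differences are not on the same scale. Unmatched random lists put 4 lists above random, with BMP and TGF-beta and WNT signalling added, and means put 2 below, dermal fibroblast and immune cell. At 100 kb BMP and TGF-beta signalling also passed, at 3.67 above random. Clusters numbered 123 with gaps under 5 kb and 1296 with gaps under 25 kb. Apart from those that the construction explains, the causes were not tested. Among the values of single lists and genes, 15 lost the threshold, 16 passed it and 24 moved beyond counting error. The gene-end odds ratio of the hair follicle stem cell list, with 0.5 added to each count, lay between 3.62 and 10.6 over its 8 alternatives and passed in each. The alternatives fixed in advance for motifs, short sequence words, forkhead sites and motif pairs, and that for knockout against control, were not run. No paired analysis was possible because the list does not separate the libraries. Depth is unknown.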

Other observations

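The gene families and the tests of dense clusters by gene family in this part were chosen after the data had been seen. Gene families, some with members in the fixed lists, differed in accessible gene ends. Only 19 of 1110 olfactory receptor genes (1.71%) and 7 of 353 vomeronasal receptor genes (1.98%) had an end peak. End peaks were also found at 4 of 56 keratin-associated protein genes and 2 of 21 late cornified envelope genes (adjusted p = 1.75e-05 over 14 families for the latter, Fisher's exact test). Small proline-rich genes, another cornified envelope family, had them in 4 of 14 cases and did not pass (adjusted p = 0.0568, Fisher's exact test). Of 53 keratin genes 16 had an end peak, including Krt5, Krt14, Krt15, Krt17, Krt6a and Krt75. Ribosomal protein genes had one in 81 of 97 cases and Frizzled receptor genes in 9 of 10, the latter not past the threshold (adjusted p = 0.0806, Fisher's exact test). Sox (63.2%), forkhead (63.6%), Wnt (57.9%), integrin (58.1%) and collagen genes (45.5%) did not pass either.

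Hair follicle stem cell genes carried more distal peaks than matched genes. Territory size was already taken into account, because the excess was measured against lists matched on it (permutation adjusted p = 0.0036). That value is the main result itself and not a separate test. A habit of transcription factor families in general is argued against. The 12 factors of the list that belong to 9 families tested stood at a mean percentile of 82.2. The 91 other members of these families stood at 51.0, but these means pool families of unlike size. Within families the list members lay on average 17.8 points above their family mean (one-sided permutation p = 0.00172). The mean of the list members was higher than that of the other members in 8 families, Gli1 being the exception. Single members outside the list could still stand higher, as Sox4 (95.2) did above Sox9 (53.3). Whether the excess may belong to wide, strong peaks only stays open: among peaks under the median width the list still lay higher, at 1.5 against 1.04, but did not pass (permutation p = 0.277), and simulations added after that result called 27% of 200 lists there with a 1.98-fold excess, that of the means over all distal peaks, and 62.5% with a 2.92-fold excess, that of the medians. No biological explanation was tested, as the list does not separate the genotypes.

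The 22 clusters of 40 or more peaks held 1766 peaks, 2.36% of those on nuclear chromosomes. Tandem families of near-identical genes are a candidate explanation that stays open: 31.8% of these clusters held 3 or more genes of a name family, above the 3.48% of equal spans placed at random but short of the majority set for the test. Genes with provisional names, such as those of the chromosome 8 clusters, could not count as a family. The share may therefore be too low, and missing the majority does not speak against this explanation. Raised read density over the whole stretch, rather than at gene ends, is consistent with the second test. Inside these clusters the peaks fell at protein-coding gene ends 0.988 times as often as when placed at random within them (SD 0.114), against 1.48 times (SD 0.0653) in the 390 clusters of 10 to 39 peaks. No biological explanation was tested for the dense clusters.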
